A study of Drosophila melanogaster with 3 samples.

How the data were processed

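The series holds 3 small RNA libraries from S2-NP cells, 1 per transfected hairpin, against dlg1, N and dpp. Per the labels, the cells received 2 µg of the UAS-shRNA plasmid and 1 µg of a pMT-Gal4 plasmid, copper sulphate was added to 500 µM on day 2, and RNA was taken 24 hours later. Cells grew at 25 °C in medium with 10% serum and 1% antibiotics. Total RNA was extracted with Trizol, size-selected by gel and sequenced on the Illumina GAII.

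The deposited files give a read count for each distinct sequence, with its length in nt and 1 annotation name chosen by the authors. Per the file headers the columns are sequence, length, name and reads, and the counts are raw and unscaled. Each length equalled that of its sequence, and each sequence was listed once. The submitters' processing notes name genome build dm3. The aligner, the order of annotations and the filters are not given in the sources used here. Reads without a name numbered 171, 140 and 92 in the dlg, N and dpp libraries, so the files hold almost only reads that matched the authors' references. The authors' names also list Flock House virus, a virus that persists in Drosophila cell lines.

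Choices of results, tests and alternatives were fixed before the data were examined, except where stated. Each hairpin was built on the known miR-1 backbone as a 5′ flank, a 21-nt passenger, loop TAGTTATATTCAAGCATA, a 21-nt guide and a 3′ flank that begins GCG. The backbone is not given in the labels, and reads cover only the flank bases next to the arms. The guide was the most abundant 20 to 24 nt read that the authors named for the 3′ arm of the hairpin, and its counts in the other libraries gave the background. A read was counted for an arm when it matched the hairpin exactly and began within 3 nt of the arm's main 5′ end, whatever its name. A count of arm reads named for a hairpin only was added after the data had been seen. Levels are reads per 1000000 counted reads (RPM) with exact Clopper-Pearson 95% intervals, and guide shares, end precision and lengths have the same kind of interval. Ratios between libraries have intervals from the exact binomial split of the pooled counts. A value of 0 was replaced by a floor of 3 counts per library for folds, which is 0.567 RPM in the dlg library, 0.636 in the N library and 0.826 in the dpp library.

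Endogenous miRNA arms were taken from the authors' names and summed over isoforms, as reads per 1000000 miRNA reads (miRNA-scaled RPM) with exact Poisson intervals. Arms with at least 100 reads over the libraries were compared as the log2 ratio of a library to the mean of the other libraries, with a pseudocount of 1 on that scale. An arm was called when it was at least 2-fold higher or lower than in each other library. No p-values were computed, since each group had 1 library. The lists of miRNAs were the K box, miR-279 and miR-92 seed families, the miR-9c cluster, the let-7 complex, Hox, muscle, neural and epithelial, embryo and ovary, S2-abundant, mirtron and other. A list's median was placed among 10000 random lists of the same size, matched on mean level. The rule for named genes took all hairpin products with up to 3 isoforms per arm, the 20 most abundant miRNA arms, up to 10 more arms past the 2-fold rule, and up to 4 members per list. The siRNA loci were named after the data had been seen, apart from esi-2.1.

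The design planned to match reads to the target genes. The genome sequence was not used here, so target reads were taken by the authors' names, which for dlg1 and N include a dsRNA entry besides the mRNAs, and those sharing at least 12 nt with the 21-nt site on either strand were set aside. The dlg1 reads were joined through exact overlaps of 14 nt, which was chosen after the data had been seen. Gene positions are from the BDGP6 annotation.

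The alternatives covered the denominator, the matching rule, a minimum of 2 reads per sequence, the 5′ window, read length, summed seed families, scaling by all counted reads, by median of ratios and by TMM (edgeR), and minimums of 30 and 300 reads. The steps were tested on simulated data. With 20000 simulated reads, the guide share was recovered within 0.00400 percentage points and the end precision within 0.111. These reads were exact pieces of the dlg hairpin, and the guide share was set rather than drawn. Recovery was therefore close to fixed and checks the counting steps only. Arms were raised in 1 library by a known fold, 200 arms per fold. Of these, 0% were called at 1.5-fold, which the 2-fold rule fixes, 95.5% at 2.5-fold and 100% at 4-fold. Of 1540 unchanged arms, counted over repeated runs on the same arms, 0 were called. They were checked only for a higher call in the library with raised arms, not for lower calls or calls in the other libraries. The simulated libraries differed by counting error alone, with no shift or extra spread between them, and lowered arms were not simulated. The rate of false calls in the real libraries is therefore not known. The tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.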

Results

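Small RNAs were sequenced from S2-NP cells, a Drosophila cell line, after transfection with a plasmid that expresses 1 short hairpin RNA (shRNA) under UAS control. There were 3 groups with 1 library each, named here after the gene that the hairpin targets. The dlg library came from the hairpin against discs large 1 (dlg1), which encodes a junction scaffold protein. The N library came from the hairpin against Notch (N), which encodes a signalling receptor, and the dpp library from the hairpin against decapentaplegic (dpp), which encodes a BMP-family ligand. The dlg library held 5286772 counted reads of 220946 distinct sequences, the N library 4715997 reads of 143599 sequences, and the dpp library 3632079 reads of 155813 sequences. Sequences seen in a single read made up 47.9% of the distinct sequences in the dlg library, 25.0% in the N library and 53.4% in the dpp library. With 1 library per group there were no replicates, so no difference between libraries could be checked against replicate error. The 95% intervals are exact Clopper-Pearson or Poisson intervals. They and the floor of 3 counts cover counting error only, since PCR reads without molecular identifiers are not independent molecules. RPM stands for reads per 1000000 counted reads, and miRNA-scaled RPM for reads per 1000000 miRNA reads.

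The first comparison asked whether each transfected hairpin gave a small RNA antisense to its target, the guide strand, and how much of it. Each library held its own guide at a high level, and the 3 levels differed widely. The dpp guide reached 80007 RPM (95% interval 79729 to 80287), the dlg guide 9437 RPM (9355 to 9520) and the N guide 3385 RPM (3333 to 3438). The dpp guide was 23.6-fold above the N guide (23.3 to 24.0) and 8.48-fold above the dlg guide (8.40 to 8.56). The dlg guide was 2.79-fold above the N guide (2.74 to 2.84). All products of the transfected hairpin together took 10.4% of the reads in the dpp library, 1.15% in the dlg library and 0.357% in the N library.

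The most abundant guide sequence was TGAATGTCCTCGTATAACCAGG for dlg with 41269 reads, TTCGGTATTGTTAACCGCCGCG for N with 14900 reads and TTTATCACTATCACTGAACGAG for dpp with 239171 reads. The target genes lie on chromosome X from 11369665 to 11409776 (dlg1, FBgn0001624), on chromosome X from 3134870 to 3172221 (N, FBgn0004647) and on chromosome 2L from 2428372 to 2459823 (dpp, FBgn0000490), all on the plus strand of build BDGP6. The genome sequence was not used here, so the target sites were not placed within exons.

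The 2 other libraries gave the background for each guide. The dlg guide had 0 reads in both, so against the floor of 3 counts it was at least 14835-fold above the N library and at least 11426-fold above the dpp library. The N guide was at least 5965-fold above the dlg library, where it had 0 reads and the same floor was used, and 1366-fold above the dpp library, where it had 9 reads. The dpp guide was 11131-fold above the dlg library, where it had 38 reads. It was 111-fold above the N library, where it had 3402 reads, or 721 RPM (697 to 746). The sources used here do not state whether the authors compared every library with all 3 hairpins, which limits the values of 0.

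**Figure D1:**
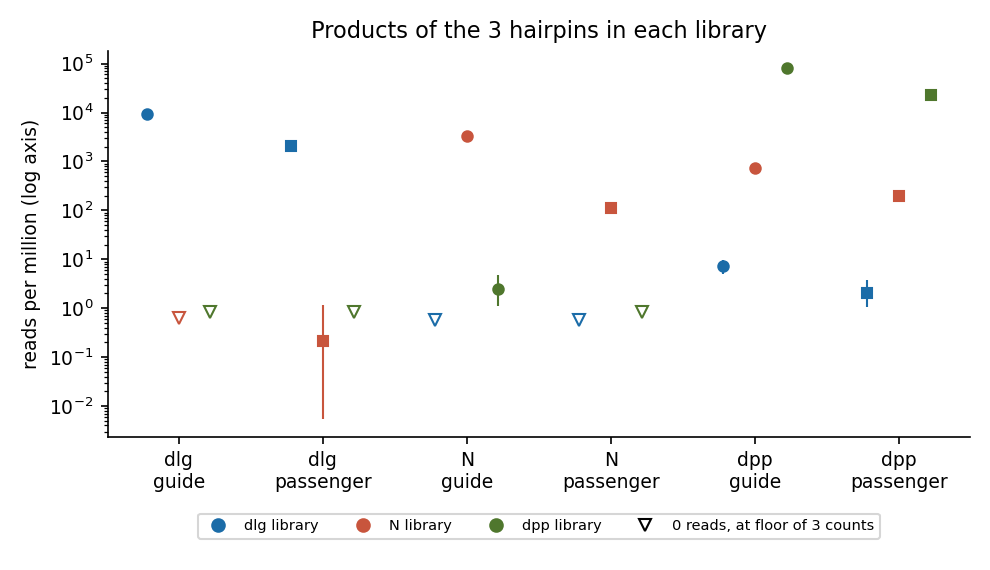
Counted reads as RPM (log axis) for the guide (circles) and passenger (squares) of each hairpin in each library, with 95% Clopper-Pearson intervals of single libraries. Open triangles mark 0 reads, drawn at the floor of 3 counts. The dpp guide stands highest at 80007 in its own library and at 721 in the N library.

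Strand choice asked how strongly the guide was kept over the passenger, the sense strand of the same duplex. All 3 hairpins gave more guide than passenger, and the N hairpin was the most asymmetric. The N guide outnumbered its passenger 30.2-fold (27.7 to 33.0), the dlg guide 4.64-fold (4.55 to 4.74) and the dpp guide 3.45-fold (3.42 to 3.48). The guide made up 96.8% of both arms for N (96.5 to 97.1), 82.3% for dlg (82.0 to 82.6) and 77.5% for dpp (77.4 to 77.7). The authors gave 2971 of the dlg passenger reads, or 27.6%, a name other than that of a hairpin, so these may not all be hairpin products. The same held for 61 N passenger reads, or 11.6%, and for 1 dpp passenger read. No guide reads carried another name, but the 21-nt dlg guide, with 6700 reads, holds no flank base. It is antisense to the dlg1 site, so its name does not show that it comes from the hairpin alone. With reads named for a hairpin only, which was chosen after the data had been seen, the guide made up 97.2% for N, 86.5% for dlg and 77.5% for dpp, and the order held. This count can take out passenger reads only, so the guide share could not fall. The dpp passenger reached 23197 RPM (23043 to 23353), the dlg passenger 2033 RPM (1994 to 2071) and the N passenger 112 RPM (103 to 122). The dpp passenger was therefore 207-fold above the N passenger (190 to 226). With the most abundant sequence alone the dpp passenger stood at 12931 RPM, the dlg passenger at 1379 RPM and the N passenger at 62.1 RPM. The most abundant passenger sequences were TGGTTATACGAGGACATTCATA for dlg with 7291 reads, CGGCGGTTAACAATACCGAATA for N with 293 reads and CGTTCAGTGATAGTGATAAATA for dpp with 46966 reads. These differences rest on 1 library for each hairpin, so the hairpin sequence and the transfection cannot be separated. Ligation bias between sequences was not measured, so the folds between strands and between hairpins are folds of reads.

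The 5′ end of the guide sets its seed, so the next comparison asked how precisely each end was made. The N guide began at its main 5′ end in 99.1% of reads (99.0 to 99.3), the dlg guide in 98.0% (97.9 to 98.1) and the dpp guide in 93.1% (93.0 to 93.2). The order of N and dlg turned when 5′ ends within 6 nt were counted, at 97.2% for N, 97.8% for dlg and 92.6% for dpp, so only the lower value of dpp is read as a difference. The dpp guide had a second 5′ end 1 nt downstream, at 6.23% of its reads, with TTATCACTATCACTGAACGAG at 16197 reads. For dlg the same offset held 1.48% of guide reads and for N it held 0.426%. The passengers began at their main end in 99.2% of reads for dlg (99.0 to 99.3), 99.4% for N (98.3 to 99.9) and 95.2% for dpp (95.1 to 95.4).

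Endogenous miRNAs of the same library gave the scale. The median over non-star arms with at least 100 reads was 99.3% in the dlg library (41 arms), 99.2% in the N library (41 arms) and 99.2% in the dpp library (39 arms). The dlg guide was more precise than 12 of these arms, the N guide than 19 and the dpp guide than 8. Star arms, named so by the authors, had medians of 97.4%, 96.6% and 96.0% in the dlg, N and dpp libraries. The dlg and N passengers were each more precise than 29 of 33 star arms, and the dpp passenger was more precise than 11 of 26.

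**Figure D2:**
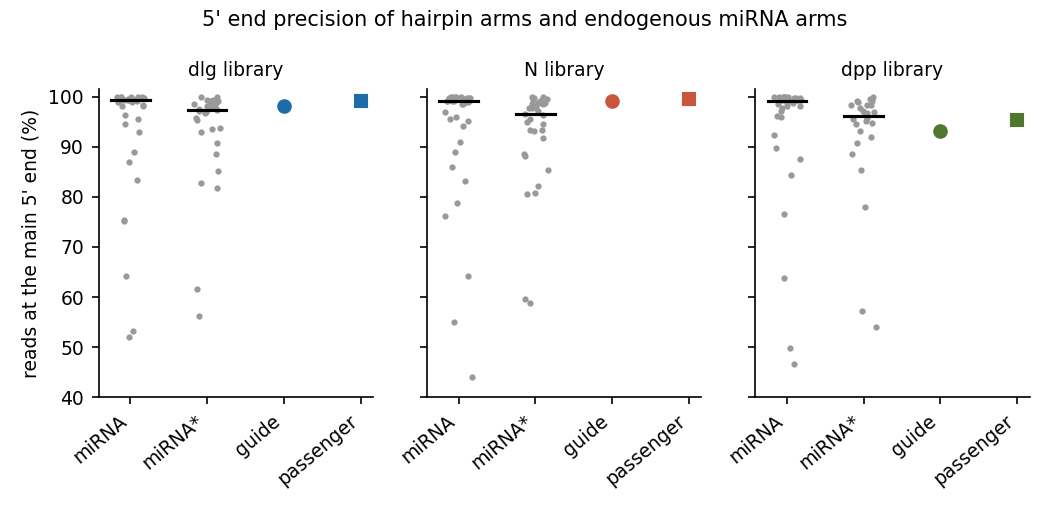
Percent of an arm's reads that begin at its main 5′ end, in each library, on an axis that starts at 40%. Grey points are endogenous miRNA and star arms with at least 100 reads, black bars their medians, and coloured symbols the hairpin's guide and passenger. The dpp guide lies at 93.1%, below the median of 99.2% of the non-star arms.

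The length comparison asked where the 3′ ends fell. At the main 5′ end, 22 nt was the main length of all 3 guides, at 84.4% of reads for dlg (84.1 to 84.7), 94.1% for N (93.8 to 94.5) and 88.4% for dpp (88.3 to 88.5). The guides were more uniform than most endogenous non-star arms, whose median share at the main length was 63.6% in the dlg library, 63.5% in the N library and 64.8% in the dpp library. Most other guide reads were 21 nt long, at 13.7% for dlg, 3.42% for N and 9.78% for dpp. The passengers were also mainly 22 nt, at 68.4% for dlg, 55.8% for N and 58.5% for dpp. The dlg passenger had a second length of 20 nt at 23.7%, whereas the second length of the N and dpp passengers was 21 nt, at 32.8% and 25.0%. The 20-nt form of dlg holds no loop base and so also matches dlg1 itself, and its 2523 reads carried a name other than that of the hairpin. A 20-nt passenger also occurred for N at 7.24%, and its 38 reads all carried another name too. For dpp it stood at 14.4%, and 0 of the 20-nt dpp reads carried another name. The names alone therefore do not show whether the second dlg length comes from the hairpin. For scale, sense dlg1 reads not lying within 3 nt of the site covered no base of the stretch assembled below more than 375 times.

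The main guide and main passenger of each hairpin formed a duplex of 20 paired nt with 2-nt 3′ overhangs at both ends. The guide ended with 1 base of the hairpin's 3′ flank, and the passenger began at base 2 of its 21-nt arm and ended with 2 bases of the loop. The 21-nt guide followed by an A, a form that differs from the hairpin, had 589 reads in the dlg library, 17 in the N library and 917 in the dpp library. These counts equalled 1.17%, 0.106% and 0.315% of the guide reads with this form included. An A there also fits the antisense strand of the hairpin, so the form cannot be read as tailing alone. Reads that began in the loop numbered 256 in the dlg library, 0 in the N library and 3 in the dpp library. Of the dlg loop reads, 249 were TAGTTATATTCAAGCATATG. The files list almost only reads that matched a reference, so loop counts are not comparable between hairpins.

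**Figure D3:**
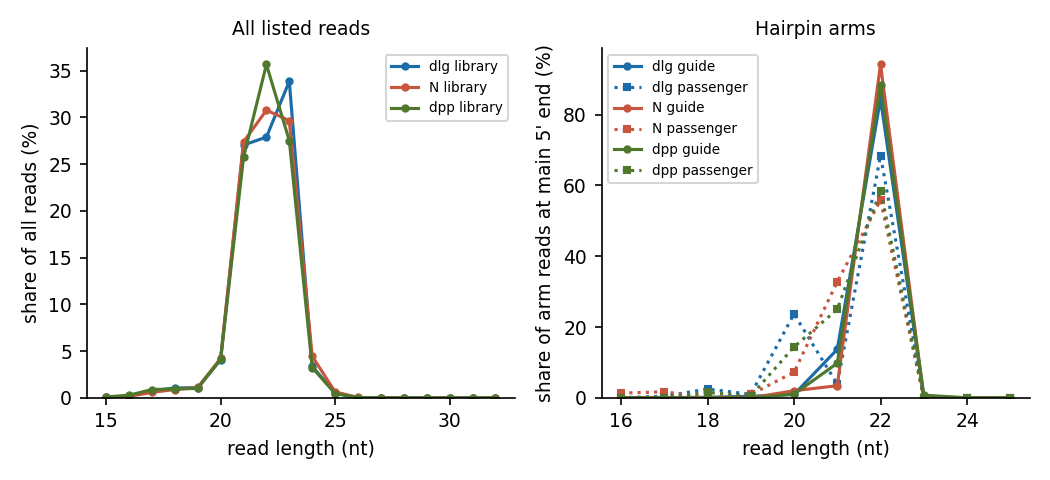
Left, percent of all counted reads by read length (nt) in each library. Right, percent of the reads at the main 5′ end by length for the guide (solid) and passenger (dotted) of each hairpin. All 3 guides peak at 22 nt, between 84.4% and 94.1%.

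Ranked against endogenous miRNAs of the same cells, the 3 guides were among the abundant small RNAs. The dpp guide ranked 3 among the 159 miRNA arms detected, below miR-184-3p with 525382 reads and above miR-980-3p with 165754 reads. The dlg guide ranked 9 among 170 arms, between miR-996-3p with 50525 reads and miR-276-5p* with 45925 reads. The N guide ranked 12 among 148 arms, between miR-11-3p with 26843 reads and miR-275-3p with 15793 reads. Relative to bantam-3p, the most abundant miRNA in these cells and known to promote growth, the dpp guide stood at 22.6%, the dlg guide at 2.37% and the N guide at 0.948%. The passengers ranked 6 for dpp, 17 for dlg and 51 for N. These ranks compare reads within 1 library, and ligation bias between sequences was not measured.

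Small RNAs from the rest of each target gene were counted to ask whether other parts of the transcript also gave small RNAs. The dlg library held 3395 reads named for dlg1 that did not overlap the site, or 642 RPM (621 to 664), and 79.9% of them were 21 nt long. The authors gave 2091 of them the name of a dlg double-stranded RNA (dsRNA) entry and 1304 the name of a dlg1 mRNA, so they are not shown to come from the dlg1 transcript. The N library held 22 dlg1 reads outside the site, 4.66 RPM (2.92 to 7.06), and the dpp library 3 reads, 0.826 RPM (0.170 to 2.41). Reads with a Notch name outside its site were more frequent in the dlg library, with 209 reads or 39.5 RPM (34.4 to 45.3), than in the N library itself, with 111 reads or 23.5 RPM (19.4 to 28.3). The dpp library held 26 Notch reads, 7.16 RPM (4.68 to 10.5). A Notch dsRNA entry gave its name to 122 of the Notch reads in the dlg library, 68 in the N library and 17 in the dpp library. Reads of the dpp gene outside its site numbered 0 in the dpp library, which by the floor of 3 counts allows up to 0.826 RPM, and 0 in the dlg library and 1 in the N library.

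The dlg1 reads of the dlg library joined into 1 stretch of 415 nt that holds the hairpin site at bases 16 to 36. Apart from reads that lie within 3 nt of the site, reads covered both strands along it, with 2164 sense and 1314 antisense, so that 62.2% were sense (60.6 to 63.8). Only 5 further dlg1 reads fell outside the stretch. The stretch was not placed in the dlg1 transcripts, which span 2102 to 7249 nt. Assembly of the stretch was chosen after the dlg1 reads had been seen.

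**Figure D4:**
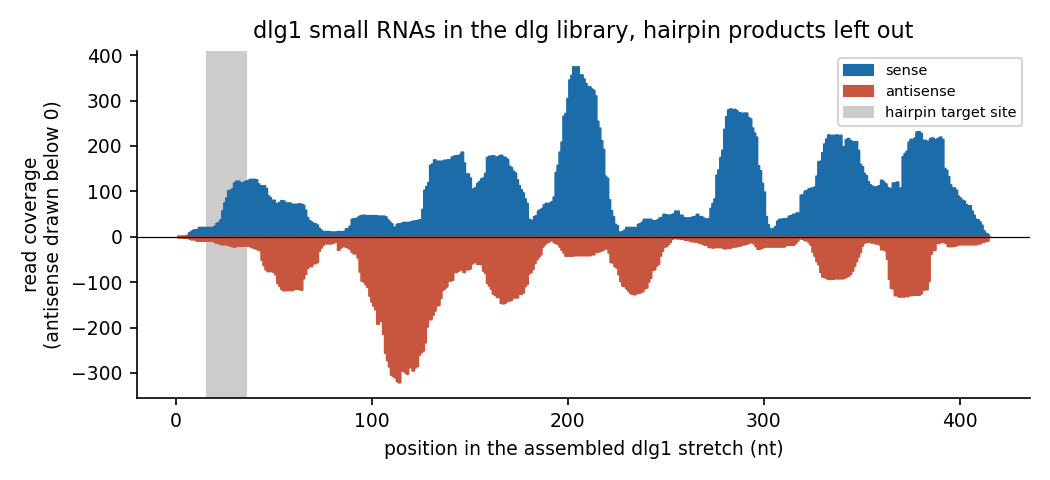
Coverage by dlg1 reads of the dlg library along the assembled stretch of 415 nt, without the reads that lie within 3 nt of the site. Sense coverage is drawn above 0 and antisense coverage below 0 (reads per position). The grey band marks the hairpin site at bases 16 to 36. Reads of both strands cover the stretch, up to 375 sense and 320 antisense.

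Endogenous miRNAs were compared to ask what else differed between the libraries. The same miRNAs dominated all 3 libraries. bantam-3p stood at 532918 miRNA-scaled RPM in the dlg library, 468489 in the N library and 507574 in the dpp library. miR-184-3p followed at 176833, 221548 and 207134, and miR-980-3p at 54010, 62440 and 65349 in the same order. The next most abundant arms were miR-2a-3p, miR-2b-3p, miR-8-3p, miR-13b-3p, miR-996-3p, miR-276-5p*, miR-34-5p, miR-11-3p, miR-275-3p, miR-9b-5p, bantam-5p*, miR-995-3p, miR-276a-3p, miR-282-5p, miR-996-5p*, miR-33-5p and miR-9c-5p. The 20 most abundant arms took 97.0% of miRNA reads in the dlg library, 97.3% in the N library and 97.4% in the dpp library. Across arms, which are not independent replicates, Pearson's r of log2 values was 0.994 between the dlg and N libraries, 0.990 between dlg and dpp, and 0.995 between N and dpp. Spearman's rho was 0.988, 0.981 and 0.991.

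Of 183 arms detected, 87 had at least 100 reads over the 3 libraries, and 2 of these were at least 2-fold apart from both other libraries. The number depended on the minimum, with 9 arms at a minimum of 30 reads and 1 arm at 300. The median log2 ratio to the mean of the other libraries was 0.23 in the dlg library, -0.01 in the N library and -0.29 in the dpp library, so changes are given relative to this shift. miR-965-5p* was lower in the dpp library, with 23 reads against 173 in the dlg library and 114 in the N library. Its log2 ratio was -1.94, or -1.66 relative to the median arm. miR-79-5p* was higher in the dlg library, with 98 reads against 40 in the N library and 26 in the dpp library. Its log2 ratio was 1.14, or 0.91 relative to the median arm, and under median of ratios scaling it was 0.90 and no longer 2-fold apart. The authors name both as star arms, and both were rare. The partner arm miR-965-3p did not share the low dpp level, at 0.13 relative to the median arm in the dpp library. The partner arm miR-79-3p lay on the same side as miR-79-5p*, at 0.67 relative to the median arm in the dlg library. Among the 20 most abundant arms, miR-995-3p had a log2 ratio of 0.54 relative to the median arm in the dlg library and -0.40 in the dpp library, and miR-184-3p had -0.51 in the dlg library and 0.34 in the dpp library. Before this adjustment miR-184-3p stood at -0.28 and 0.06. The adjusted signs of miR-184-3p were shared by all arms of rank 1 to 6, such as miR-980-3p at -0.47 and 0.45 and miR-8-3p at -0.34 and 0.10. They are therefore not particular to miR-184-3p. In simulated data with counting error alone, 95.5% of arms raised 2.5-fold in 1 library were called, and lowered arms were not simulated. The real libraries also differed by the shifts above, so this share need not hold for them. By construction the rule calls no difference under 2-fold.

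**Figure D5:**
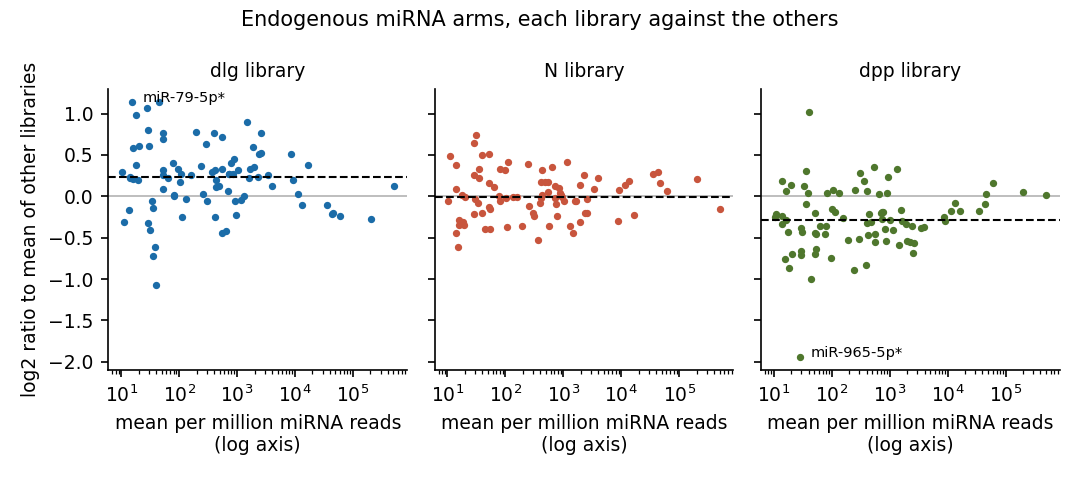
Log2 ratio of each library to the mean of the other libraries for the 87 miRNA arms, against mean miRNA-scaled RPM (log axis). Dashed lines mark the median arm, at 0.23 for dlg, -0.01 for N and -0.29 for dpp. The 2 named points are the arms at least 2-fold apart from both other libraries.

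Of the arms with at least 100 reads in the lists of miRNAs fixed beforehand, 0 were at least 2-fold apart from both other libraries, while the Hox, let-7, miR-92 and muscle lists had no arm with that many reads. At a minimum of 30 reads 3 listed arms were, namely miR-3-3p, miR-31a-5p and miR-278-3p, named after their values had been seen. A list's median is set against random lists of the same size and abundance, and 21 such percentiles were computed. For the K box seed family, whose members share the seed of miR-2, 6 of 7 detected arms were tested. Its median stood at the 0.97 percentile in the N library, with log2 ratios of 0.16 for miR-2a-3p, 0.29 for miR-2b-3p, -0.22 for miR-13b-3p and -0.30 for miR-11-3p, so its 2 most abundant members lay on the other side of 0. In the dlg and dpp libraries the family stood at the 77.3 and 81.8 percentiles. The neural and epithelial list, with miR-7-5p, miR-987-5p and miR-263a-5p tested, stood at the 24.0, 97.4 and 16.5 percentiles in the dlg, N and dpp libraries. The miR-279 seed family, with miR-996-3p and miR-279-3p, stood at 3.60, 66.3 and 96.3 in the same order.

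The list of miRNAs known to be abundant in S2 cells had 18 tested arms, led by bantam-3p, miR-184-3p, miR-980-3p and miR-8-3p, at the 38.8, 48.0 and 71.3 percentiles. The miR-9c cluster had 4 tested arms (miR-9b-5p, miR-9c-5p, miR-79-3p and miR-306-5p) at 57.6, 17.8 and 42.0. The embryo and ovary list had 3 tested arms (miR-318-3p, miR-994-5p and miR-5-5p) at 60.6, 65.5 and 29.6. The remaining list of other miRNAs had 8 tested arms, led by miR-307-3p, miR-999-3p, miR-252-5p and miR-281-1-3p, at 12.4, 48.2 and 80.2. The muscle miRNA miR-1-3p, whose precursor gave the hairpin backbone, had 1 read in the dlg library, 4 in the N library and 3 in the dpp library. let-7-5p of the let-7 complex had 22, 31 and 25 reads, miR-92b-3p of the miR-92 seed family 6, 3 and 6 reads, and the listed Hox cluster arms (miR-10-5p, miR-iab-4-5p and miR-993-3p) 0 reads in every library. miR-10-3p*, the other arm of miR-10, had 4 reads in the dlg library, 0 in the N library and 3 in the dpp library.

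Endogenous siRNA loci and mirtrons were compared as other Dicer products of the same cells. None of 17 siRNA loci and 1 mirtron was at least 2-fold apart from both other libraries. The largest locus was klar, a gene of nuclear and lipid droplet transport on chromosome 3L, with 84839 miRNA-scaled RPM in the dlg library (84552 to 85126), 82908 in the N library and 75813 in the dpp library. The transposon mdg1 gave 35305, 34345 and 33042 miRNA-scaled RPM in the same order. The hairpin siRNA locus esi-1 gave 3590, 3203 and 2655, and the siRNA esi-2.1 gave 1444, 1414 and 1169. The mirtron miR-1003-3p, made from a spliced intron, had 89 reads in the dlg library, 130 in the N library and 154 in the dpp library. Its log2 ratio was 1.02 in the dpp library, or 1.31 relative to the median arm, and -1.07 in the dlg library, or -1.30 relative to the median arm. In both libraries miR-1003-3p was less than 2-fold apart from the N library. The other arm of the same mirtron, miR-1003-5p*, had 215, 235 and 93 reads in the dlg, N and dpp libraries. Its log2 ratio was -0.69 in the dpp library and 0.09 in the dlg library. The arms did not move together, so no direction is read for the mirtron. The median log2 ratio of the 17 loci was 0.10 in the dlg library, 0.04 in the N library and -0.12 in the dpp library. These medians changed sign under other scalings, to -0.16 in the dlg library and 0.15 in the dpp library under median of ratios and to -0.05 in the N library under TMM, so no direction is read from them. The loci were chosen after the data had been seen, apart from esi-2.1.

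The make-up of the libraries was described by class and length. miRNAs took 74.7% of reads in the dlg library, 76.2% in the N library and 69.8% in the dpp library, but 0.813%, 0.983% and 0.985% of the distinct sequences. Products of the transfected hairpin took 1.15%, 0.357% and 10.4% of reads in the same order. By construction they lower every other share of reads in the dpp library, so the lower dpp shares here are not read as a fall. Names of transposons, which are silenced by siRNAs and piRNAs, took 9.0%, 8.92% and 7.66%, and the klar locus 6.34%, 6.32% and 5.29%. Names of other protein-coding genes took 4.81%, 4.61% and 3.97%. Fragments of tRNA took 0.751%, 0.516% and 0.489%, and reads with an rRNA name numbered 4, 1 and 0. The main length of all counted reads was 23 nt in the dlg library at 33.9%, and 22 nt in the N and dpp libraries at 30.8% and 35.7%. Without the hairpin reads, the dpp library had 31.0% at 22 nt and 30.6% at 23 nt, so these lengths were close. Classes follow the authors' single name for each sequence, and nearly all counted reads carried a name, so the shares describe the listed reads.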

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

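All tests in this part were chosen only after the result was seen. The results below are signals in reads outside the main measurement, above the limit that a count of 0 allows.

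The N library held 3402 reads of the dpp guide and the dlg library 38, while the dpp library held 9 reads of the N guide. The dpp guide in the N library stood at 1.17% of its own-library count (1.13 to 1.21). An exchange of reads in both directions would carry the N guide into the dpp library at a like share, but that share was 0.0564% (0.0258 to 0.107), which argues against it. The dpp reads in the N library had a guide share of 78.3% (77.1 to 79.6), against 77.5% in the dpp library (77.4 to 77.7), as carry-over of dpp construct, RNA or library in 1 direction would give. A small amount of dpp construct taken up by the N cells predicts the same share, so these cannot be told apart, and no biological explanation was tested.

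Reads of the v gene (vermilion, an eye-pigment gene used as a marker in fly vectors) numbered 11928 in the dlg library, 9380 in the N library and 3842 in the dpp library. A general fall of siRNAs in the dpp library may be proposed, but the log2 ratio of v was -0.89 (-0.94 to -0.85) and the lowest of 17 siRNA loci was -0.36, so such a fall does not account for the whole of it. Outside those loci, histone gene names stood at -0.67 and Flock House virus RNA1 at -0.37, so v was not alone in being low, and it lay below the 17 loci also when scaled by all counted reads, by median of ratios (-0.62 against -0.08) and by TMM (-0.70 against -0.16). The labels do not name the vector, so the origin of the v reads and any link to plasmid amount stay open, and no biological explanation was tested.

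Reads named for hairpins against white, an eye-colour gene that no library targeted, numbered 10 in the N library and 4 in the dpp library. The dlg library held 1 such read, which is not above the floor of 3 counts.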

How the results depend on the processing

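Every alternative in this part was planned, except the one with reads named for a hairpin only, which was chosen after the data had been seen. No paired analysis was possible because the labels give 1 library per group and no shared replicate numbers. Of 141 alternative values, 80 stayed within the counting interval or limit of the reported value, 56 moved beyond it and 5 changed sign. The order of the 3 guides in abundance, the excess of guide over passenger and the main guide length of 22 nt held under every alternative run for them. Intervals here are narrow because counts are large, so small moves count as moved. For all values below the cause was not tested, except that another denominator or subset changes the value by construction.

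Guide levels for dlg, N and dpp were 12631, 4440 and 114567 per 1000000 miRNA reads, and 7806, 3159 and 65850 for the top sequence alone. For dlg and dpp they were 9528 and 81025 per 1000000 reads of 18 to 30 nt, 9683 and 80343 with 1 mismatch or added bases, and 9629 and 81880 for sequences with at least 2 reads. The guide share with 20 to 24 nt reads was 82.7% for dlg and 77.9% for dpp, and with 1 mismatch 82.6% for dlg. With reads named for a hairpin only it was 86.5% for dlg and 97.2% for N, and the passengers stood at 1471 and 99.0 RPM. The passengers of dlg, N and dpp stood at 1379, 62.1 and 12931 RPM with the top sequence alone. Precision of the dlg, N and dpp guide was 98.4%, 99.5% and 93.7% in a window of 1 nt and 97.8%, 97.2% and 92.6% in a window of 6 nt, where N fell below dlg, and with 20 to 24 nt reads 98.3% for dlg and 93.2% for dpp. The 22-nt share over all 5′ ends was 82.8%, 93.5% and 82.5%. With seed families summed the dlg guide ranked 7 and the N guide 11, and with single isoforms the N guide ranked 10.

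The number of miRNA arms at least 2-fold apart was 2 as reported, 1 under median of ratios, 9 with a minimum of 30 reads, of which miR-982-5p was called in 2 libraries, and 1 with a minimum of 300. miRNAs were 0.813%, 0.983% and 0.985% of distinct sequences in the dlg, N and dpp libraries, and 76.2%, 76.8% and 71.5% of reads in sequences seen at least 2 times. Reads of the transfected hairpin are part of these totals. The dlg1 reads outside the site fell to 3116 with a site widened by 25 nt. The median of 17 siRNA loci changed sign to -0.16 in the dlg library and 0.15 in the dpp library under median of ratios, and to -0.000759, -0.0474 and 0.0733 in the dlg, N and dpp libraries under TMM. Matching target genes with 1 mismatch was not run, since the genome sequence was not used here. Depth limits a count of 0 to 3 counts, and single libraries leave the variation between transfections unknown.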

Other observations

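All tests in this part were chosen only after the result was seen.

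Many 21-nt reads came from a virus and from genes of the cells. Reads named for Flock House virus, a virus that persists in Drosophila cell lines, made up 2.06% of the dlg library (2.05 to 2.07), 1.89% of the N library (1.87 to 1.90) and 1.42% of the dpp library (1.41 to 1.44). Of these, 84.5%, 83.6% and 83.4% were 21 nt long, close to the 80.4% of klar reads in the dlg library and far from the 2.64% of tRNA reads there. Hairpin reads lower the share of the virus in the dpp library. Per 1000000 miRNA reads the virus also stood lowest there, at 27600, 24750 and 20397 in the dlg, N and dpp libraries. On this scale the median miRNA arm also lay at a log2 ratio of -0.29 in the dpp library, near virus RNA1 at -0.37 and RNA2 at -0.34. The virus was not scaled in other ways, so no fall of the virus is read from these values. The gene pyd, which encodes a junction protein, gave 8785, 8423 and 7922 reads per 1000000 miRNA reads in the dlg, N and dpp libraries. The gene dnt, which encodes a receptor tyrosine kinase of the Ryk family, gave 6458, 6171 and 6053, and Sema-1a, an axon guidance gene, gave 2909, 2796 and 2539.

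The dlg1 reads outside the hairpin site were weighed as a pattern, as 3395 reads that shared no 12-nt stretch with the site. Small RNAs along the whole transcript would cover most of it, but the joined dlg1 reads of the dlg library, which hold every base that these reads cover, were together 518 nt long, or 24.6% of the shortest dlg1 transcript, which argues against it. Long double-stranded RNA of the main stretch of 415 nt is a candidate explanation, because the authors named 2091 of the 3395 reads for a dlg dsRNA entry, 79.9% of the 3395 were 21 nt long (78.6 to 81.3) and 37.8% of the 3478 stretch reads apart from those within 3 nt of the site lay on the antisense strand. The source of such RNA, whether dsRNA given to the cells earlier, material carried over or the cells' own, was not tested, and the names show a sequence match only.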
